A study of Homo sapiens with 9 samples.

How the data were processed

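RNA was measured in 9 libraries, 3 in each of 3 groups of macrophages. Per the labels' protocols, THP-1 cells, a human monocytic leukaemia line, were turned into macrophages with the phorbol ester PMA (50 ng/mL, 24 h). They were then kept for 48 h in the lower chamber of a Transwell plate, with HK-2 cells, an immortalized line of human kidney proximal tubule cells, on the membrane above. In the control group the HK-2 cells were unmodified. In the other groups the HK-2 cells carried a knockdown of VHL, and the macrophages were sorted by an antibody to APOE into fractions with high (APOEhi) or low (APOElo) staining. Macrophages of all 3 groups, control included, went through staining and sorting. Poly(A)-selected, stranded libraries were read as 150 bp pairs, per the labels' protocols. Each group holds replicates that the labels number alike, and nothing says that they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

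Per the submitters' processing notes, the tools were fastp 0.20.0, FastQC 0.11.9, HISAT2 2.1.0 and featureCounts of Subread 2.0.1, with the genome build GRCh38.p13. Their settings, including whether reads were counted by strand, are not given in the sources used here. It is therefore not known whether reads from genes that overlap on opposite strands were kept apart. The authors deposited 2 comparison tables, APOEhi against control and APOElo against control, each made from 6 libraries. Per the file headers, a table gives for every gene a mean normalized count over its 6 libraries, which is a signal that is never negative. The authors' log2 fold change and its standard error (SE) stand beside it. The authors' statistic, a score without a fixed range, is the log2 fold change divided by its standard error. The last columns are the authors' deposited p-value and its adjusted p-value, per the file headers. The column names are those that DESeq2 writes, but the tool the authors used is not named in the sources used here. The tables give comparisons and no column of values per library. An own fit of the libraries, as laid down before the data were examined, could therefore not be run, and the authors' fold changes and adjusted p-values were used in its place.

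The APOEhi table lists 33256 genes, of which 21558 have an adjusted p-value, and the APOElo table lists 33747 and 21861. The lowest mean normalized count with an adjusted p-value is 1.82 and 1.89, respectively. A symbol was missing for 8776 and 9026 genes, and 298 and 304 of these were filled from the reference annotation by gene identifier. Of the identifiers, 31444 and 31912 occur in that annotation, 18189 and 18546 with the same start and end. Coordinates are printed as the authors' tables give them.

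The tables were normalized separately. Sequencing depth was recovered from genes with a single read in a single library, whose mean normalized count is set by that library's size factor alone. Between 465 and 676 such genes per library gave the 6 size factors of each table, and the order of the replicates is not known. The level of a gene in each group was derived from its mean and its fold change. For 31704 genes in both tables the control level could be derived from each of them. The 13968 genes with a mean normalized count of at least 20 in each table were compared. The control levels of the tables differed by a log2 ratio of -0.06 at the median, which is the gap between the separate normalizations. Among the 13919 genes whose entries passed the other checks, the deviation from this gap had a standard deviation of 0.00229 and a maximum of 0.0235, so the same control libraries stand in both tables.

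Each entry was checked for whether the fold change equals the statistic times the standard error (tolerance 1e-06), whether the p-value follows from the statistic, whether the adjusted p-value follows from the p-values within 1%, whether the mean is shared with the other table, and whether the control levels differ by no more than 0.3. Entries that failed were set aside, 41 in the APOEhi table and 32 in the APOElo table, from 50 genes. This was decided after the tables were seen. Tests therefore cover 21517 genes for APOEhi, 21829 for APOElo and 20959 for both.

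A gene was called at an adjusted p below 0.05. The change in APOEhi was compared with that in APOElo by the difference of the log2 fold changes. Its standard error was taken from both standard errors as if they were independent, with a normal test and Benjamini-Hochberg adjustment. The controls are shared, so this standard error is an upper bound and the test is conservative. The plan written before the data were examined left this comparison untested if the tables were normalized separately. It was added after the tables were seen, because the control libraries are the same and a constant gap between the normalizations leaves fold changes as they are. Data were simulated for 20959 genes, with 50 genes each changed by a log2 difference of 0.5, 1, 2 and 3. The difference test called 22, 34, 50 and 50 of these, and 0 of 20759 unchanged genes. The changed genes were drawn from those with a mean normalized count above 20 for APOEhi. Genes with lower counts are therefore not covered. Errors were drawn as normal with the listed standard errors, so few calls among unchanged genes were built in.

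The 33 gene lists were fixed before the data were examined and cover lipid handling, inflammation, antigen presentation, matrix, stress, metabolism, cell cycle, RNA quality and other cell types. Lists with at least 5 tested members were tested by cameraPR of limma 3.58.1 in R 4.3.3 on the statistic of each gene, two-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. A correlation could not be estimated without values per library. In simulated lists of 20 members among the 21517 genes of the APOEhi comparison, 6 of 200 lists with no shift, 116 with a shift of 0.5 standard deviations and 196 with a shift of 1 had an unadjusted p below 0.05. The simulated lists were drawn from statistics shuffled over genes, so their members were uncorrelated. Their rates do not cover lists whose members change together. Counts of members that rose or fell are also given adjusted over the list alone. Other steps ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

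Named genes follow a rule written before the data were examined. APOE comes first. Then come the 7 genes with the largest rise and the 7 with the largest fall among called genes with a group mean of at least 5 CPM, derived from its level. For up to 8 lists per comparison, in order of the list test, up to 3 called members with the largest change in the prevailing direction and 1 in the other direction follow. Lists of other cell types and of RNA quality give up to 2 members by level, and the lists of LXR targets and lipid uptake may be named throughout. The part of the rule that asks for no overlap between the groups could not be checked without values per library. A member named outside the rule is said to be chosen after its values were seen. For genes with few reads in control, read numbers were rebuilt from the levels and size factors, and a fitted value under 0.75 was taken as 0 reads, a bound set after the fitted values were seen. A fold against 0 reads is given against a floor of 3 reads over the 3 libraries of the group together. Ratios with up to 3 reads have an exact 95% Clopper-Pearson interval. Intervals and floors cover counting error only, since reads copied by PCR are not independent molecules.

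Alternatives were other filters on low counts, scaling by library totals, median-centred fold changes, a minimum log2 fold change of 1, entries set aside put back, protein-coding genes only, shared control error removed from the difference, and other list statistics. Fits that need values per library were not run. Some genes that the rules select are not reported here, in the text or in the figures, and they remain in the counts and lists. Expression of VHL in the HK-2 cells was not analysed here.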

Results

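RNA was sequenced from sorted THP-1 macrophages of 3 groups with 3 libraries each. Control macrophages had shared medium with unmodified HK-2 kidney tubule cells. APOEhi and APOElo macrophages had shared medium with HK-2 cells in which VHL was knocked down, and were separated by their staining for APOE, a lipid carrier of lipoproteins. VHL is the tumour suppressor whose product marks hypoxia-inducible factors for degradation. By size, the control libraries held about 14.4 M, 15.8 M and 19.4 M counted reads, the APOEhi libraries 17.3 M, 17.3 M and 20.7 M, and the APOElo libraries 16.8 M, 17.8 M and 18.9 M. For genes with a mean of at least 100 normalized counts, the median SE of a log2 fold change in the authors' deposited tables was 0.11 for APOEhi (10718 genes) and 0.09 for APOElo (10874 genes). The comparisons ask how macrophages with high and with low APOE staining differ from control macrophages and from each other, with lipid handling in view. Against control, the HK-2 partner and the APOE fraction change together. A difference from control can therefore not be assigned to either of them.

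Some entries of the authors' deposited tables were not internally consistent. In 39 entries of the APOEhi table and 31 of the APOElo table, from 49 genes, the listed log2 fold change was not the statistic times its standard error. The listed value was the higher of the pair in 47 entries and the lower in 23. By table, it was higher in 19 and lower in 20 entries for APOEhi, and higher in 28 and lower in 3 for APOElo. Of 21 genes with such a gap in both tables, 19 were listed too low in APOEhi and too high in APOElo, relative to statistic times SE. The gap was a multiple of 0.1 within 1e-05 in 54 of the 70 entries and a whole number in 26, and the signs differed in 5. In the authors' deposited table for APOEhi, the chemokine gene CXCL10 was listed at 0.90 where statistic times SE gives -4.90. CXCL10 was listed at 2.01 in the authors' deposited table for APOElo where statistic times SE gives -2.01. NFKBIA, an inhibitor of NF-kB, was listed at 0.59 in APOEhi and 1.95 in APOElo in the authors' deposited tables, where statistic times SE gives 1.46 and 0.95. These genes were chosen after their values were seen. Of 49 genes with such or other faults whose control level could be derived from both tables, the levels disagreed by more than 0.3 (log2) for 44 with the listed fold changes and for 5 with statistic times SE. Those 5 were APOE, CD163, TGFB1, TGFBR1 and TGFBR2. No gene among the 13919 without another fault disagreed by that much. These entries were set aside from every count, list and comparison that follows, among them 6 of the 25 genes for cholesterol synthesis.

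**Figure D1:**
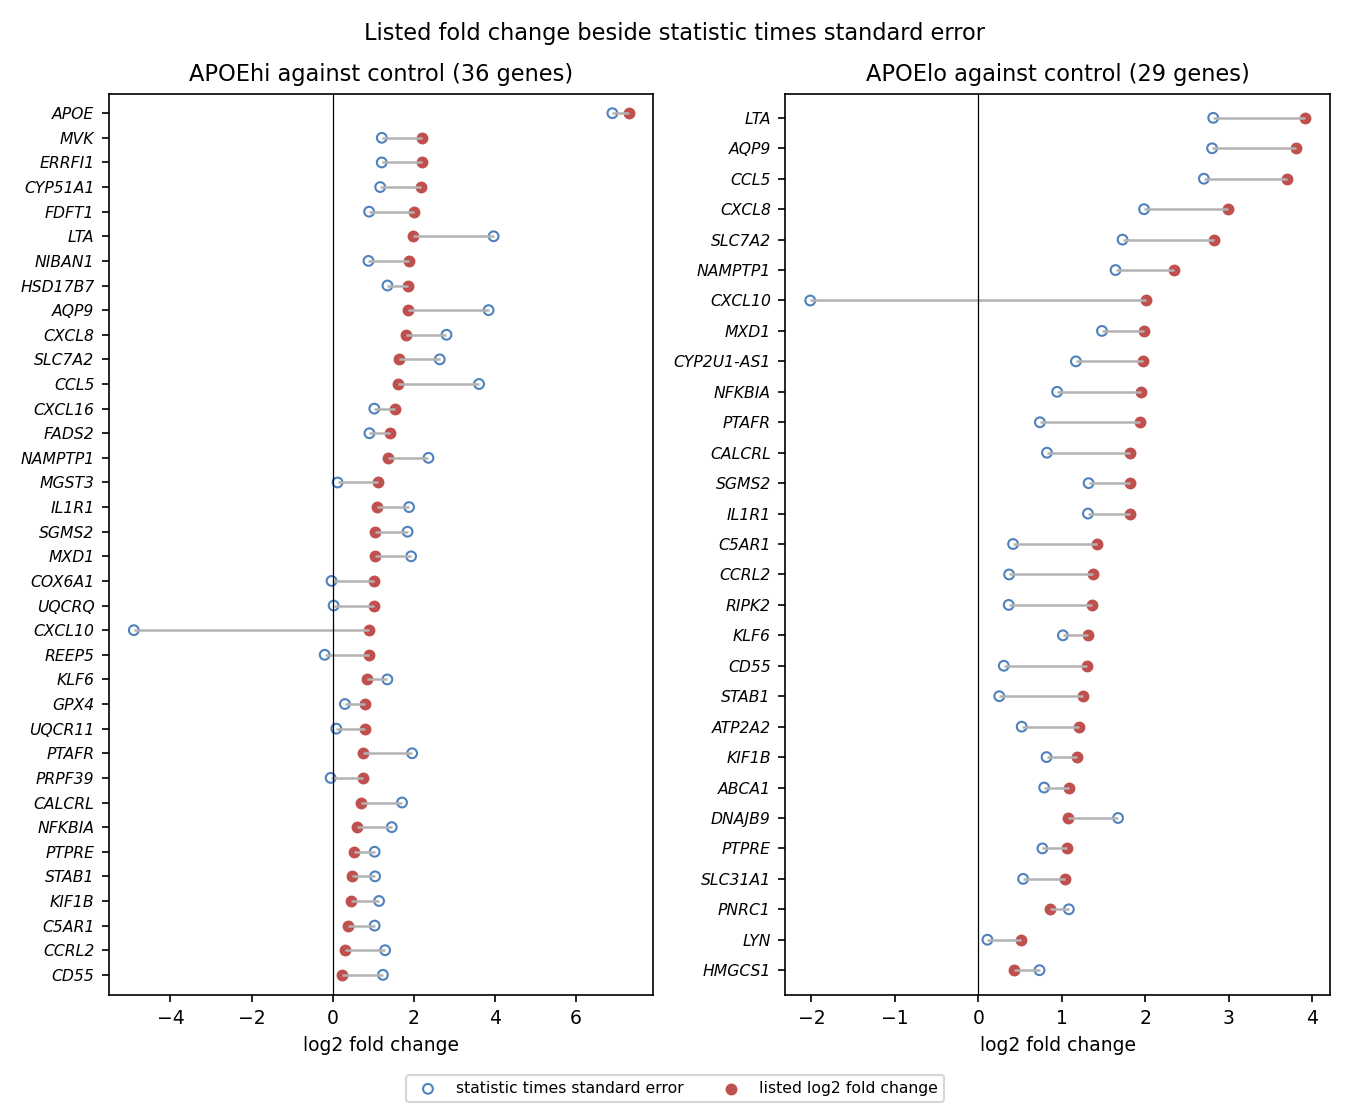
Log2 fold change against control listed in the authors' deposited tables (filled points) and the product of the listed statistic and standard error (open points), 1 line per gene, for genes where they differ by at least 0.05. In APOEhi, CXCL10 is listed at 0.90 and its statistic times SE is -4.90.

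APOE itself (ENSG00000130203, chromosome 19, 44905791 to 44909393, plus strand, GRCh38) was the gene product used for sorting. The authors' deposited tables listed it at a log2 fold change of 7.30 (SE 0.74, adjusted p = 2.9e-19) in APOEhi and 0.81 (SE 0.11, adjusted p = 5.1e-13) in APOElo. Both entries share 1 mean normalized count, 3546, although the tables were normalized separately. The control level derived from them is 44.7 in the APOEhi table and 2574 in the APOElo table, a log2 deviation of -5.79 in libraries whose genes without a fault deviate by at most 0.0235. The statistic times SE gives 6.90 for APOEhi. With the control level taken from the other table, the log2 fold change is 1.51 in APOEhi and 6.60 in APOElo. Between APOEhi and APOElo the listed values of the authors' deposited tables differ by 6.49, while the levels of the separately normalized tables set side by side differ by 0.70. The level of APOE RNA in the sorted fractions is therefore not settled by these tables and does not check the labels.

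APOEhi against control asks how macrophages with high APOE staining from the VHL-knockdown co-culture differ from control macrophages. The largest rises were in SERPINB4, a serine protease inhibitor of squamous epithelia, and in CCL26, a chemokine for eosinophils. SERPINB4 (ENSG00000206073, chromosome 18, 63637259 to 63644256, minus strand) had 2 reads in control and 15197 in APOEhi, a log2 fold change of 12.89 in the authors' deposited table (SE 1.02) with a 95% counting interval from 11.04 to 15.94. CCL26 (chromosome 7, 75769533 to 75789896, minus strand) had 0 reads in control and 2098 in APOEhi, at least 700.4-fold higher. SERPINB3, a near-identical neighbour of SERPINB4 whose reads can be shared with it, had 0 and 1226 reads, at least 409-fold higher. The macrophage elastase gene MMP12 had 3 reads in control and 1141 in APOEhi, at 8.57 (SE 0.84) in the authors' deposited table with an interval from 7.02 to 10.85.

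CCL13, a monocyte chemokine, and the immediate-early genes FOSB and NR4A3 followed at 7.99 (SE 0.40), 7.92 (SE 0.39) and 7.73 (SE 0.43) in the authors' deposited table. At the other end the authors' deposited table listed SERPINB2, the plasminogen activator inhibitor of macrophages, at -5.71 (SE 0.68), OLIG1 at -4.79 (SE 0.26), the myeloid progenitor gene MS4A3 at -4.49 (SE 0.35), the interferon-induced gene IFIT1 at -4.47 (SE 0.15) and the stem cell factor receptor KIT at -4.29 (SE 0.35). PID1 and IFI44L stood at -4.13 (SE 0.25) and -4.02 (SE 0.40) in the authors' deposited table. In all, 7954 of 21517 genes were called in APOEhi, 4177 higher and 3777 lower.

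All 23 tested genes of the unfolded protein and amino acid stress response rose in APOEhi (23 adjusted over the list alone), with a median of 1.24 (cameraPR, adjusted p = 6.9e-65). ATF3, a stress-induced transcription factor, stood at 4.20 (SE 0.09), the ER chaperone partner DNAJB9 at 3.01 (SE 0.08) and DDIT3, which encodes CHOP, at 2.76 (SE 0.10) in the authors' deposited table. The list of heat shock and tissue dissociation genes rose as a set with a median of 0.56 (16 of 27 rose and 6 fell, also 16 and 6 adjusted over the list alone, cameraPR, adjusted p = 1.0e-08). Its members included the immediate-early genes EGR3 at 5.18 (SE 0.47), NR4A1 at 5.15 (SE 0.50) and FOS at -2.22 (SE 0.08) in the authors' deposited table. The abundant heat shock genes HSPA8 and HSP90AA1 stood at -0.99 (SE 0.07) and, without a call, 0.02 (SE 0.07) in the authors' deposited table, so they did not share the rise of the set.

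Cholesterol synthesis genes, LXR targets and genes of lipid-associated macrophages rose as sets in APOEhi. Of 19 tested cholesterol synthesis genes, 15 rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 0.80 (cameraPR, adjusted p = 5.5e-20). INSIG1, a regulator of sterol synthesis, stood at 2.02 (SE 0.07), the sterol carrier STARD4 at 1.93 (SE 0.09) and PMVK at -0.40 (SE 0.13) in the authors' deposited table. Of 14 LXR targets and efflux genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone, median 0.64, cameraPR, adjusted p = 1.2e-04). SREBF1 stood at 1.36 (SE 0.09), the cholesterol exporters ABCG1 at 1.12 (SE 0.11) and ABCA1 at 1.02 (SE 0.24), and PLTP at -0.43 (SE 0.12) in the authors' deposited table. Of 15 genes of lipid-associated macrophages, 9 rose and 2 fell (9 and 4 adjusted over the list alone, median 0.49, cameraPR, adjusted p = 6.2e-09). Lipoprotein lipase (LPL) stood at 2.60 (SE 0.07), the lysosomal lipase LIPA at 1.61 (SE 0.07), the lipid droplet coat PLIN2 at 1.25 (SE 0.08) and CD9 at -0.95 (SE 0.15) in the authors' deposited table. The span listed for LIPA overlaps IFIT genes on the opposite strand, so its value is uncertain.

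Fatty acid synthesis rose as a set in APOEhi (6 of 11 rose and 2 fell, likewise adjusted over the list alone, median 0.81, cameraPR, adjusted p = 7.1e-04). Lipid uptake and scavenger receptors went both ways, with 6 of 13 up and 4 down, likewise adjusted over the list alone. Their median was 0.13, or -0.02 after scaling by library totals, and cameraPR gave a rise (adjusted p = 2.1e-04). The fatty acid carrier FABP4 stood at 2.40 (SE 0.10) and the oxidized lipoprotein receptor OLR1 at 1.66 (SE 0.10), against CD36 at -0.69 (SE 0.07), MSR1 at -0.73 (SE 0.09) and MARCO at -2.72 (SE 0.33), in the authors' deposited table. Lipid droplet genes (6 of 17 up and 4 down, 7 and 4 adjusted over the list alone, median 0.11, adjusted p = 0.324) and fatty acid oxidation (6 of 19 up and 4 down, 7 and 4 adjusted over the list alone, median 0.18, adjusted p = 0.619) did not pass cameraPR.

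Genes of alternative activation rose as a set in APOEhi (9 of 17 rose and 5 fell, likewise adjusted over the list alone, median 0.75, cameraPR, adjusted p = 8.0e-20). Transglutaminase 2 (TGM2) stood at 5.09 (SE 0.08), the lipoxygenase ALOX15 at 4.98 (SE 0.15), fibronectin (FN1) at 4.23 (SE 0.21) and the complement receptor VSIG4 at -0.83 (SE 0.08) in the authors' deposited table. Matrix genes rose as a set (9 of 19 rose and 3 fell, 10 and 4 adjusted over the list alone, median 0.39, cameraPR, adjusted p = 3.4e-07). NF-kB targets also rose (14 of 21 rose and 2 fell, 16 and 3 adjusted over the list alone, median 0.72, cameraPR, adjusted p = 0.00183). Of MHC class II genes 6 of 11 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.72, cameraPR, adjusted p = 0.0312). Hypoxia targets rose as a set (13 of 28 rose and 3 fell, 14 and 3 adjusted over the list alone, median 0.51, cameraPR, adjusted p = 6.2e-04), as did NRF2 targets (12 of 19 and 2, likewise adjusted over the list alone, median 0.30, adjusted p = 0.00992).

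Interferon-induced genes fell in APOEhi, 28 of 32 with 1 rise (likewise adjusted over the list alone), with a median of -2.01 (cameraPR, adjusted p = 7.3e-61). IFIT1 and IFI44L were joined by the chemokine CXCL11 at -4.16 (SE 0.67), and the transcription factor IRF1 stood at 0.46 (SE 0.08), in the authors' deposited table. Progenitor-type myeloid genes fell in 11 of 13 cases with 1 rise (likewise adjusted over the list alone, median -2.15, cameraPR, adjusted p = 2.4e-23). MYB, a transcription factor of blood progenitors, stood at -3.17 (SE 0.09) and the cytokine receptor FLT3 at 0.43 (SE 0.09) in the authors' deposited table. Of 18 macrophage identity genes 11 fell and 3 rose (likewise adjusted over the list alone, median -0.70, cameraPR, adjusted p = 2.0e-08). Lysozyme (LYZ) stood at -3.98 (SE 0.07), the oxidase subunit CYBB at -1.48 (SE 0.08) and the integrin ITGAM at 1.32 (SE 0.07) in the authors' deposited table. MHC class I genes fell in 11 of 15 cases with 0 rises (likewise adjusted over the list alone, median -0.40, cameraPR, adjusted p = 1.2e-04).

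Genes of the mitochondrial genome rose as a set in APOEhi (11 of 13 rose and 0 fell, 13 and 0 adjusted over the list alone, median 0.61, cameraPR, adjusted p = 6.5e-05). MT-ND4 stood at 0.65 (SE 0.11) and MT-CO1 at 0.47 (SE 0.10) in the authors' deposited table. The citric acid cycle list also passed (10 of 18 rose and 1 fell, 12 and 1 adjusted over the list alone, median 0.24, cameraPR, adjusted p = 0.0371). Of markers of other cell types, 1 of 18 renal epithelial genes rose and 4 fell (likewise adjusted over the list alone, median -0.57, cameraPR, adjusted p = 0.334). Of 9 fibroblast and endothelial genes 0 rose and 4 fell (likewise adjusted over the list alone, median -0.42, cameraPR, adjusted p = 0.297). PECAM1, an adhesion gene on the latter list, stood at -0.63 (SE 0.07) in the authors' deposited table.

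In APOEhi, cameraPR called 19 of the 33 lists, and alternatives other than fold changes in place of the statistic ended the call for alternative activation (adjusted p up to 0.212), fatty acid synthesis (0.228), lipid uptake (0.380), MHC class II (0.102), the citric acid cycle (0.204) and NRF2 targets (0.0639). With fold changes in place of the statistic 11 of these calls ended and stress, interferon, progenitor-type, cholesterol synthesis, alternative activation, matrix, hypoxia and heat shock genes passed, as did renal epithelial genes, which were lower (adjusted p = 0.0476). Scaling by library totals lowers every APOEhi log2 fold change by 0.15 and gives 8312 calls, 2879 higher and 5433 lower (34.6% higher, against 52.5% with the authors' size factors). The balance also turned with median-centred fold changes (3703 higher and 4278 lower) and at a minimum log2 fold change of 1 (1127 higher and 1293 lower).

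APOElo against control asks the same of macrophages with low APOE staining. SERPINB4, CCL26, SERPINB3 and MMP12 led again. SERPINB4 had 2 reads in control and 6143 in APOElo, at 11.48 (SE 1.02) in the authors' deposited table with a 95% counting interval from 9.62 to 14.52. CCL26 had 0 and 731 reads, at least 226-fold higher, and SERPINB3 had 0 and 542, at least 168-fold higher. MMP12 stood at 7.37 (SE 0.85, interval 5.82 to 9.65), FOSB at 6.63 (SE 0.39), CCL13 at 6.60 (SE 0.40) and NR4A3 at 6.58 (SE 0.43) in the authors' deposited table.

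The largest falls in APOElo were in MS4A3 at -4.89 (SE 0.37), the retinol dehydrogenase DHRS9 at -4.80 (SE 0.21), LYZ at -4.43 (SE 0.06), SERPINB2 at -4.14 (SE 0.42), the scavenger receptor COLEC12 at -4.09 (SE 0.14), the calcium channel subunit CACNA2D3 at -4.03 (SE 0.31) and the pore-forming protein MPEG1 at -4.00 (SE 0.13) in the authors' deposited table. Of 21829 genes tested, 8012 were called, 4125 higher and 3887 lower.

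Interferon-induced genes fell in APOElo too, 28 of 32 with 0 rises (likewise adjusted over the list alone, median -1.39, cameraPR, adjusted p = 1.4e-63). MX1 stood at -3.49 (SE 0.09), IFIT1 at -3.47 (SE 0.11) and IFIT2 at -3.25 (SE 0.13) in the authors' deposited table. All 13 progenitor-type genes fell (13 adjusted over the list alone, median -2.14, cameraPR, adjusted p = 2.9e-34), among them the granule protease CTSG at -3.67 (SE 0.12) and MYB at -3.17 (SE 0.08) in the authors' deposited table. Of 18 macrophage identity genes 14 fell and 3 rose (likewise adjusted over the list alone, median -0.88, cameraPR, adjusted p = 6.2e-22). AIF1 stood at -1.52 (SE 0.15) and ITGAM at 0.77 (SE 0.06) in the authors' deposited table.

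Lysosomal genes fell in APOElo, 20 of 26 with 3 rises (likewise adjusted over the list alone, median -0.35, cameraPR, adjusted p = 4.5e-10). The proteases CTSD and CTSS stood at -1.08 (SE 0.06) and -0.85 (SE 0.04), and the cholesterol transporter NPC1 at 0.50 (SE 0.08), in the authors' deposited table. MHC class I genes fell in 12 of 15 cases with 0 rises (likewise adjusted over the list alone, median -0.73, cameraPR, adjusted p = 4.8e-11). HLA-F stood at -1.48 (SE 0.13), HLA-C at -0.99 (SE 0.08) and HLA-B at -0.97 (SE 0.07) in the authors' deposited table. Complement genes fell in 10 of 13 cases with 3 rises (likewise adjusted over the list alone, median -0.68, cameraPR, adjusted p = 0.00323). Nuclear genes of oxidative phosphorylation fell in 22 of 37 cases with 1 rise (likewise adjusted over the list alone, median -0.23, cameraPR, adjusted p = 0.0140), and cytosolic ribosomal genes in 16 of 37 with 0 rises (18 and 0 adjusted over the list alone, median -0.20, cameraPR, adjusted p = 0.0142).

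Matrix genes rose in APOElo (12 of 19 rose and 3 fell, likewise adjusted over the list alone, median 0.41, cameraPR, adjusted p = 2.0e-14). The protease gene MMP7 stood at 4.51 (SE 0.11) and MMP1 at 4.31 (SE 0.21), FN1 at 4.02 (SE 0.13) and TIMP2 at -0.47 (SE 0.05) in the authors' deposited table. NF-kB targets rose (15 of 21 rose and 1 fell, 15 and 2 adjusted over the list alone, median 0.77, cameraPR, adjusted p = 6.7e-09). The cytokine IL1B stood at 2.75 (SE 0.14), the chemokine CCL20 at 2.02 (SE 0.13), the adhesion molecule ICAM1 at 1.87 (SE 0.06) and NFKBIZ at -0.51 (SE 0.09) in the authors' deposited table. The unfolded protein and amino acid stress list rose (15 of 22 rose and 4 fell, likewise adjusted over the list alone, median 0.42, cameraPR, adjusted p = 9.2e-14). ATF3 stood at 3.34 (SE 0.08), HERPUD1 at 1.54 (SE 0.04), DDIT3 at 1.49 (SE 0.08) and CRELD2 at -0.70 (SE 0.07) in the authors' deposited table. Heat shock and dissociation genes rose as a set (16 of 27 rose and 7 fell, likewise adjusted over the list alone, median 0.34, cameraPR, adjusted p = 4.3e-05), and so did cell cycle genes (19 of 28 rose and 3 fell, 21 and 3 adjusted over the list alone, median 0.22, cameraPR, adjusted p = 6.6e-04) and p53 targets (10 of 18 rose and 4 fell, 11 and 4 adjusted over the list alone, median 0.30, cameraPR, adjusted p = 0.00125).

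Lipid genes changed in both directions in APOElo. Of 23 cholesterol synthesis genes 13 rose and 3 fell (14 and 3 adjusted over the list alone, median 0.34, cameraPR, adjusted p = 4.3e-05), and of 12 LXR targets 5 rose and 1 fell (likewise adjusted over the list alone, median 0.22, cameraPR, adjusted p = 0.0481). ABCG1 stood at 1.09 (SE 0.10), SREBF1 at 0.81 (SE 0.08) and PLTP at -0.82 (SE 0.11) in the authors' deposited table. Of 15 lipid-associated macrophage genes 5 rose and 7 fell (likewise adjusted over the list alone). Their median was -0.07 while their mean was 0.12 and cameraPR gave a rise (adjusted p = 0.00213), so the median goes against the test. Alternative activation likewise went both ways (8 of 17 rose and 5 fell, likewise adjusted over the list alone, median 0.09, cameraPR, adjusted p = 1.2e-08). TGM2 stood at 4.05 (SE 0.06) and VSIG4 at -1.69 (SE 0.07) in the authors' deposited table. Lipid uptake genes did not pass (5 of 14 rose and 6 fell, likewise adjusted over the list alone, adjusted p = 0.826 by cameraPR), and their median of -0.05 lay opposite to the direction cameraPR gave. OLR1 stood at 2.12 (SE 0.09), FABP4 at 0.85 (SE 0.07), CD36 at -1.15 (SE 0.04), MARCO at -2.54 (SE 0.30) and CD68 at -1.13 (SE 0.24) in the authors' deposited table. Fatty acid synthesis rose (6 of 12 rose and 3 fell, 6 and 4 adjusted over the list alone, median 0.24, cameraPR, adjusted p = 0.00123).

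Hypoxia targets passed in APOElo as well (11 of 28 rose and 5 fell, 11 and 6 adjusted over the list alone, median 0.17, cameraPR, adjusted p = 0.0149), and so did the mitochondrial genome (9 of 13 rose and 1 fell, 10 and 1 adjusted over the list alone, median 0.22, cameraPR, adjusted p = 0.0142). Of 19 renal epithelial genes 6 rose and 1 fell (likewise adjusted over the list alone), with a median of 0.59 that did not pass cameraPR (adjusted p = 0.490). The 6 were CDH1 with 0 control reads, CLDN1 at 3.22, MET at 1.66, CAV1 at 0.99, CDH2 at 0.93 and PAX8 at 0.80 in the authors' deposited table, chosen after their values were seen. Of 9 fibroblast and endothelial genes 2 rose and 2 fell (likewise adjusted over the list alone, median 0.42, cameraPR, adjusted p = 0.195). PDGFRA, a growth factor receptor of fibroblasts, stood at 3.49 (SE 0.15) in the authors' deposited table.

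In APOElo, cameraPR called 21 of the 33 lists, and alternatives other than fold changes in place of the statistic ended the call for alternative activation (adjusted p up to 0.372), lipid-associated macrophages (0.689), fatty acid synthesis (0.256), LXR targets (0.115), hypoxia (0.0557) and complement (0.119). With fold changes in place of the statistic 12 of these calls ended, and the 9 lists that passed were interferon, progenitor-type, macrophage identity, MHC class I, complement, NF-kB, alternative activation, matrix and heat shock genes.

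**Figure D2:**
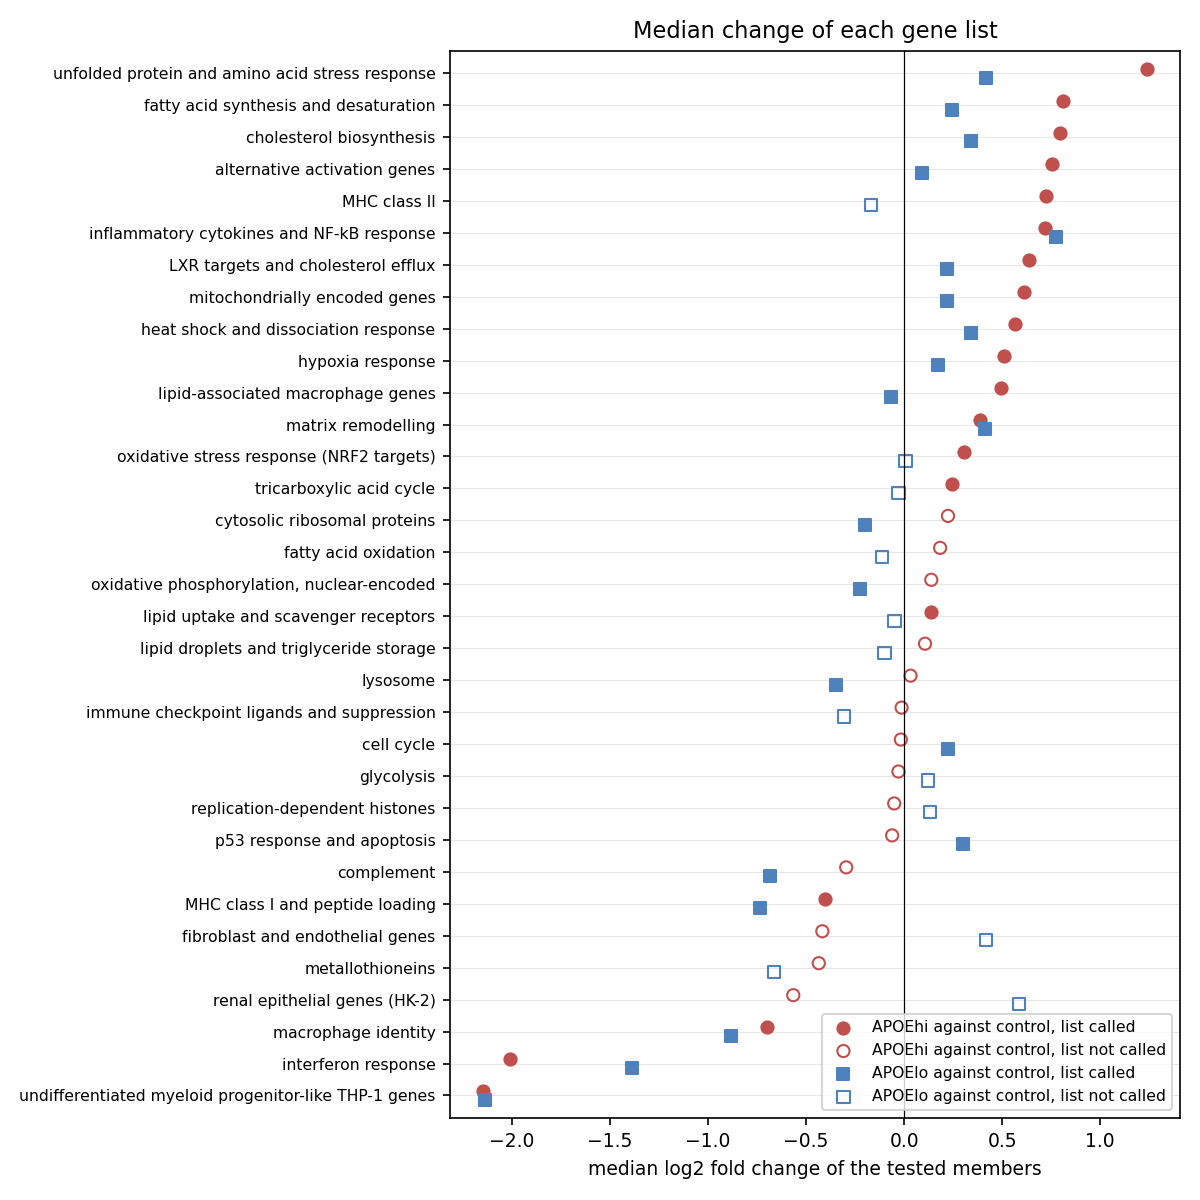
Median log2 fold change against control over the tested members of each of the 33 gene lists, for APOEhi (circles) and APOElo (squares), filled where cameraPR called the list. Progenitor-type genes lie at -2.15 and -2.14 and the unfolded protein and amino acid stress list at 1.24 and 0.42, and the APOEhi medians for lipid uptake, lipid droplets, lysosome and oxidative phosphorylation turn negative when scaled by library totals.

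Called in both comparisons were 4922 of the 20959 genes tested in both. Of these, 2263 were higher and 2249 lower in both, and 410 went in opposite directions. Of the 4512 changed in the same direction, MYB was listed at -3.17 in both of the authors' deposited tables, while 1217 changed by different amounts, 845 of them more in APOEhi and 372 more in APOElo. Independent lists of these sizes would share 1488 genes in the same direction (788 higher and 700 lower). Unchanged groups set against the same controls shared 0 in 100 simulated draws, a count that is near 0 by construction, since an adjusted test makes few calls without an effect. Across genes, which are not independent replicates, the fold changes correlated at 0.67, against 0.44 for unchanged groups with these controls. The covariance was 0.58 against a simulated 0.12, a difference of 0.46. With 3 control libraries no split leaves both parts with a pair, so part of the overlap beyond 1488 may come from the shared controls.

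**Figure D3:**
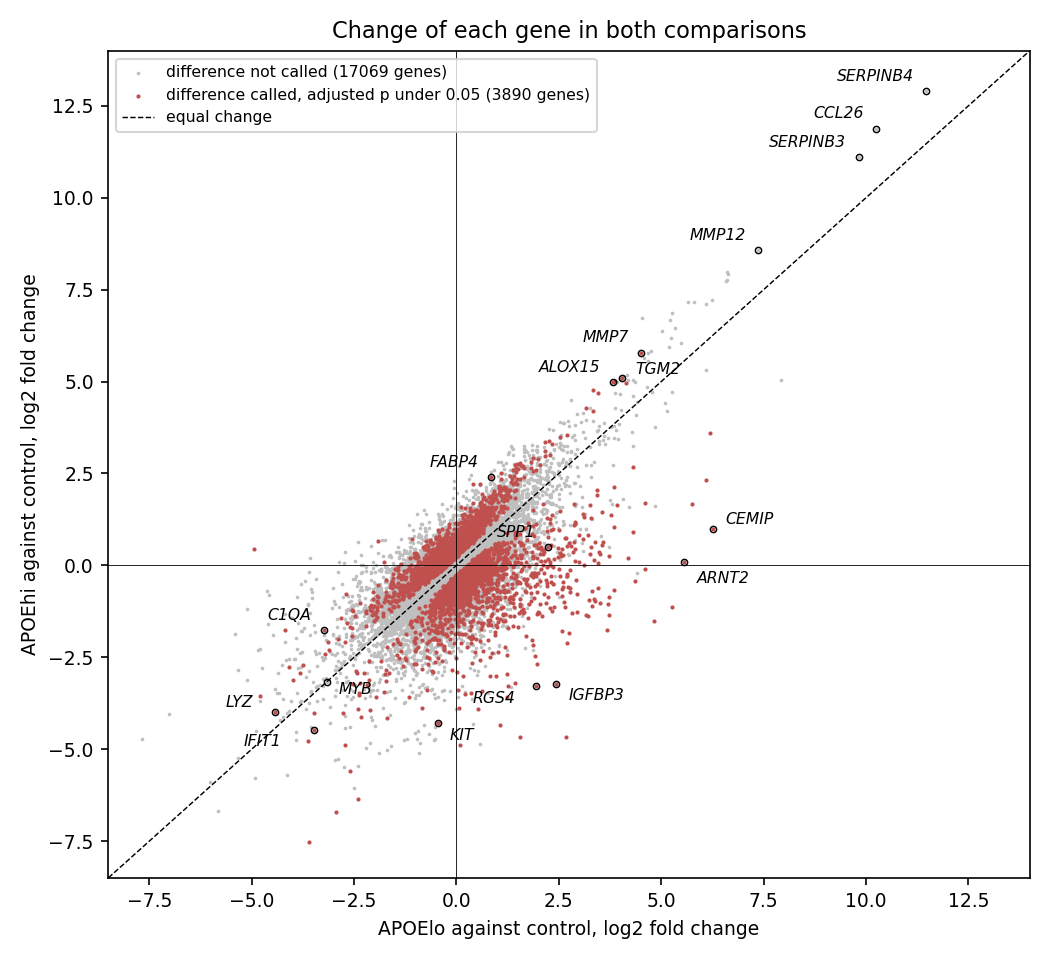
Log2 fold change against control in APOElo (horizontal) and APOEhi (vertical) for each of 20959 genes, as listed in the authors' deposited tables. Red points mark the 3890 genes whose difference was called, and IGFBP3 and RGS4 lie below 0 in APOEhi and above 0 in APOElo.

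APOEhi against APOElo asks what separates macrophages with high and low APOE staining from the same co-culture. The largest differences were in genes higher in APOElo. IGFBP3, a binding protein of insulin-like growth factors (ENSG00000146674, chromosome 7, 45912245 to 45921874, minus strand), fell in APOEhi and rose in APOElo, at -3.22 (SE 0.12) and 2.44 (SE 0.06) in the authors' deposited tables, a difference of -5.66 (SE 0.13). The signalling regulator RGS4 stood at -3.28 (SE 0.30) and 1.93 (SE 0.12) in the authors' deposited tables, a difference of -5.22 (SE 0.32, adjusted p = 6.3e-56). CEMIP, which takes part in hyaluronan breakdown, stood at 1.00 (SE 0.35) and 6.27 (SE 0.19) in the authors' deposited tables, a difference of -5.27 (SE 0.40).

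TSPAN18, ARNT2 and the endothelial gene PLVAP differed by -6.32 (SE 1.17), -5.47 (SE 0.55) and -5.07 (SE 0.87). Markers of other cell types moved the same way, with a median difference of -0.62 for renal epithelial genes and -0.93 for fibroblast and endothelial genes. In the other direction FABP4 differed by 1.55 (SE 0.12), with 2.40 (SE 0.10) in APOEhi and 0.85 (SE 0.07) in APOElo in the authors' deposited tables. The complement protease C1S differed by 1.80 (SE 0.43), C1QA by 1.48 (SE 0.21), the ER protein SDF2L1 by 1.48 (SE 0.24), the protease inhibitor SPINT2 by 1.42 (SE 0.18), the calcium-binding protein S100A8 by 1.39 (SE 0.24) and RAB20 by 1.37 (SE 0.16). C1QA fell less in APOEhi, at -1.76 (SE 0.11), than in APOElo, at -3.24 (SE 0.18), in the authors' deposited tables. Of 20959 genes 3890 differed, 2202 higher and 1688 lower in APOEhi.

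Differences in the unfolded protein and amino acid stress list were all towards higher values in APOEhi (20 of 22, likewise adjusted over the list alone, median 0.91, cameraPR, adjusted p = 7.1e-39). The ER chaperone CRELD2 stood at 0.53 (SE 0.10) in APOEhi and -0.70 (SE 0.07) in APOElo in the authors' deposited tables, a difference of 1.23 (SE 0.12), and MANF and DDIT3 each differed by 1.27 (SE 0.11 and SE 0.13). Lysosomal genes were higher in 19 of 26 cases (21 adjusted over the list alone, 0 lower, median 0.42, cameraPR, adjusted p = 3.4e-15). CTSL stood at a difference of 0.89 (SE 0.10), CTSD at 0.86 (SE 0.12) and CTSB at 0.81 (SE 0.08). Of 18 cholesterol synthesis genes 11 were higher and 0 lower (17 and 0 adjusted over the list alone, median 0.57, cameraPR, adjusted p = 2.0e-11). STARD4 stood at a difference of 0.96 (SE 0.12) and MVD at 0.91 (SE 0.15).

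Lipid uptake genes were higher in APOEhi in 9 of 13 cases with 1 lower (likewise adjusted over the list alone, median 0.56, cameraPR, adjusted p = 1.6e-08). FABP4 was followed by CD68 at 1.00 (SE 0.33), LRP1 at 0.68 (SE 0.12), FABP5 at 0.56 (SE 0.14) and CD36 at 0.46 (SE 0.08), with OLR1 at -0.46 (SE 0.14). Of lipid-associated macrophage genes 11 of 15 were higher and 1 lower (11 and 2 adjusted over the list alone, median 0.65, cameraPR, adjusted p = 9.6e-08). LIPA stood at a difference of 0.97 (SE 0.08), PLIN2 at 0.69 (SE 0.09), LPL at 0.66 (SE 0.08) and osteopontin (SPP1) at -1.75 (SE 0.09). Of 12 LXR targets 5 were higher and 0 lower (6 and 0 adjusted over the list alone, median 0.28, cameraPR, adjusted p = 0.00701). APOC1 stood at a difference of 0.72 (SE 0.12), SMPDL3A at 0.70 (SE 0.14) and NR1H3, which encodes an LXR, at 0.66 (SE 0.13). Fatty acid synthesis (6 of 11 higher and 1 lower, 6 and 2 adjusted over the list alone, median 0.34, cameraPR, adjusted p = 0.0373) and fatty acid oxidation (10 of 19 higher and 2 lower, 12 and 2 adjusted over the list alone, median 0.40, cameraPR, adjusted p = 0.00187) were also higher as sets.

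Alternative activation genes were higher in APOEhi in 12 of 17 cases with 2 lower (likewise adjusted over the list alone, median 1.04, cameraPR, adjusted p = 5.5e-08). The chemokines CCL22 and CCL24 differed by 1.38 (SE 0.31) and 1.26 (SE 0.26), the folate receptor FOLR2 by 1.25 (SE 0.37), and IL1RN, the interleukin 1 receptor antagonist, by -1.10 (SE 0.12). MHC class II genes were higher in 8 of 11 cases with 0 lower (9 and 0 adjusted over the list alone, median 1.00, cameraPR, adjusted p = 1.2e-05). HLA-DPA1 stood at a difference of 1.24 (SE 0.46), HLA-DMB at 1.18 (SE 0.25) and HLA-DRA at 1.18 (SE 0.20). Complement genes (8 of 13 higher and 1 lower, likewise adjusted over the list alone, median 0.58, cameraPR, adjusted p = 0.00119) and macrophage identity genes (8 of 18 higher and 2 lower, 9 and 2 adjusted over the list alone, median 0.21, cameraPR, adjusted p = 0.00635) were higher as sets.

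Cytosolic ribosomal genes were higher in APOEhi in 21 of 37 cases with 0 lower (30 and 0 adjusted over the list alone, median 0.42, cameraPR, adjusted p = 5.5e-08). RPS2 stood at a difference of 0.51 (SE 0.11) and RPL4 at 0.49 (SE 0.10). Nuclear genes of oxidative phosphorylation (13 of 36 higher and 0 lower, 18 and 0 adjusted over the list alone, median 0.32, cameraPR, adjusted p = 1.8e-05), the mitochondrial genome (9 of 13 and 0, likewise adjusted over the list alone, median 0.37, adjusted p = 2.4e-05), NRF2 targets (9 of 19 and 1, 11 and 2 adjusted over the list alone, median 0.42, adjusted p = 9.6e-05) and the citric acid cycle (6 of 18 and 1, 9 and 1 adjusted over the list alone, median 0.25, adjusted p = 0.00408) were higher too. Heat shock and dissociation genes were higher as a set (11 of 27 higher and 5 lower, 12 and 6 adjusted over the list alone, median 0.43, cameraPR, adjusted p = 0.0257).

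Sets that were lower in APOEhi than in APOElo were the cell cycle (12 of 28 lower and 0 higher, 13 and 0 adjusted over the list alone, median -0.18, cameraPR, adjusted p = 1.2e-04), NF-kB targets (7 of 21 lower and 2 higher, 8 and 2 adjusted over the list alone, median -0.15, adjusted p = 0.00635) and interferon-induced genes (9 of 32 lower and 3 higher, 10 and 3 adjusted over the list alone, median -0.18, adjusted p = 0.0178). IL1B differed by -2.14 (SE 0.24), CCL20 by -1.40 (SE 0.22) and IFIT1 by -0.99 (SE 0.19). Matrix genes passed cameraPR with lower values (adjusted p = 0.0427) and a mean of -0.04, but their median was 0.26 (5 of 19 higher and 6 lower, 5 and 7 adjusted over the list alone), with MMP7 at 1.27 (SE 0.16) and MMP1 at -1.63 (SE 0.33). Renal epithelial genes were lower in 5 of 18 cases with 0 higher (likewise adjusted over the list alone, median -0.62, cameraPR, adjusted p = 0.0332), and fibroblast and endothelial genes in 2 of 8 with 0 higher (likewise adjusted over the list alone, median -0.93, cameraPR, adjusted p = 0.00214). PDGFRA stood at a difference of -3.12 (SE 0.29).

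In this comparison cameraPR called 24 of the 33 lists, 12 with fold changes in place of the statistic. The call ended under at least 1 other alternative for fatty acid synthesis (adjusted p up to 0.173), NF-kB targets (0.0821), interferon (0.0625), matrix (0.810), renal epithelial genes (0.131), macrophage identity (0.105), heat shock (0.133) and the citric acid cycle (0.0703), and fibroblast and endothelial genes could not be tested with a minimum of 10 in both group means. After scaling by library totals 1123 genes were higher and 2786 lower (28.7% higher, against 56.6%). Lower genes were also the larger part with median-centred fold changes (1748 higher and 1966 lower) and at a minimum log2 difference of 1 (165 higher and 658 lower).

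**Figure D4:**
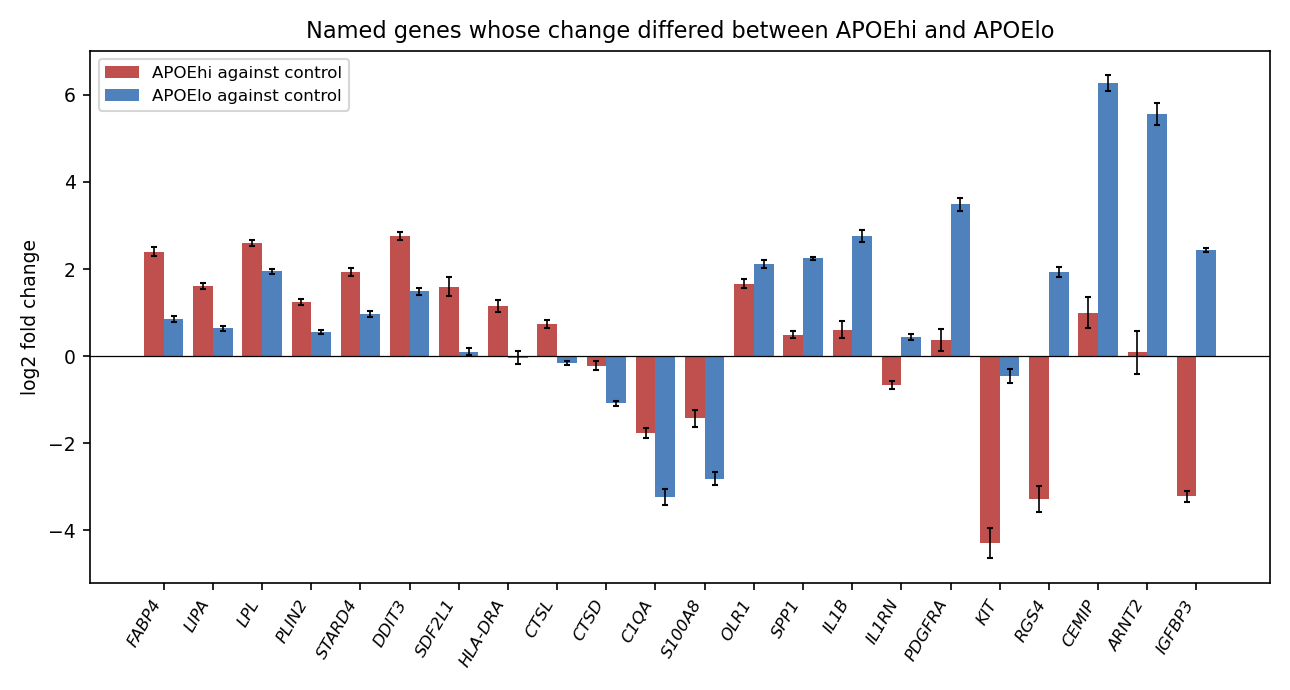
Log2 fold change against control of 22 named genes in APOEhi (red) and APOElo (blue), with the SE of the authors' deposited tables as error bars. IGFBP3 and RGS4 lie on opposite sides of 0, with differences of -5.66 and -5.22.

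Other lists did not pass cameraPR in the reported setting. In APOEhi, 9 of 26 lysosomal genes rose and 5 fell (10 and 7 adjusted over the list alone, median 0.03, adjusted p = 0.297). Of nuclear oxidative phosphorylation genes 10 of 36 rose and 0 fell (9 and 0 adjusted over the list alone, median 0.14, adjusted p = 0.288). Of cytosolic ribosomal genes 12 of 37 rose and 0 fell (likewise adjusted over the list alone, median 0.22, adjusted p = 0.0564). Of complement genes 4 of 13 rose and 6 fell (5 and 6 adjusted over the list alone, median -0.30, adjusted p = 0.467). Of cell cycle genes 7 of 28 rose and 7 fell (likewise adjusted over the list alone, median -0.02, adjusted p = 0.999). Of p53 targets 7 of 18 rose and 3 fell (7 and 4 adjusted over the list alone, adjusted p = 0.0792), and their median of -0.06 lay opposite to their mean and to the direction cameraPR gave. Cytosolic ribosomal genes (adjusted p = 4.6e-05) and oxidative phosphorylation (0.0232) passed with ranks of the statistic, and cytosolic ribosomal genes (0.0104) and p53 targets (0.0193) without the filter on low counts.

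In APOElo, 1 of 11 MHC class II genes rose and 5 fell (likewise adjusted over the list alone, median -0.17, adjusted p = 0.135 by cameraPR). Of NRF2 targets 5 of 19 rose and 7 fell (5 and 8 adjusted over the list alone, median 0.01, adjusted p = 0.725). Of fatty acid oxidation genes 2 of 19 rose and 9 fell (likewise adjusted over the list alone, median -0.11, adjusted p = 0.0749). Of citric acid cycle genes 2 of 18 rose and 2 fell (likewise adjusted over the list alone, median -0.03, adjusted p = 0.964). Between APOEhi and APOElo the lists for progenitor-type genes (adjusted p = 0.842), MHC class I (adjusted p = 0.194), hypoxia (adjusted p = 0.10) and p53 targets (adjusted p = 0.208) did not pass. Lipid droplets, glycolysis, immune checkpoint genes, metallothioneins and histones passed cameraPR in none of the 3 comparisons in the reported setting. Ranks of the statistic added calls for fatty acid oxidation (lower, adjusted p = 0.0425) and metallothioneins (lower, 0.0430) in APOElo, and for hypoxia (higher, 0.0459) between APOEhi and APOElo. Leaving out the filter on low counts added fatty acid oxidation (lower, 0.0261) and glycolysis (higher, 0.0234) in APOElo, and hypoxia (higher, 0.0310) and lipid droplets (higher, 0.0386) between APOEhi and APOElo.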

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

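The test of the difference between the changes in APOEhi and APOElo was chosen only after the tables were seen. With it, 3890 genes and 24 gene lists changed by different amounts in APOEhi and APOElo. Of the genes called against control in both, 410 went in opposite directions, each with a called difference. Among called lists whose medians and cameraPR directions against control were both opposite, none of them called in both, fatty acid oxidation differed by a median of 0.40 (APOEhi minus APOElo, log2), lysosomal genes by 0.42, MHC class II genes by 1.00, nuclear oxidative phosphorylation genes by 0.32, the tricarboxylic acid cycle by 0.25 and cytosolic ribosomal genes by 0.42. The cell cycle list differed by -0.18, renal epithelial genes by -0.62, and fibroblast and endothelial genes by -0.93. Tested by cameraPR on fold changes, the differences of fatty acid oxidation (adjusted p = 0.0646), the tricarboxylic acid cycle (0.210) and the cell cycle list (0.349) were not called. Scaled by library totals, the APOEhi medians of lysosomal and oxidative phosphorylation genes were -0.12 and -0.02, on the side of APOElo, and cameraPR gave fatty acid oxidation the lower direction in APOEhi (adjusted p = 0.997). The APOEhi median of the cell cycle list (-0.02) and the APOElo median of the tricarboxylic acid cycle (-0.03) lay near 0.

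Named single genes that rose in APOEhi and fell in APOElo were the cytokine receptor FLT3 (difference 0.98, SE 0.12), the ER chaperone CRELD2 (1.23, SE 0.12) and the lysosomal protease CTSL (0.89, SE 0.10). Named genes that fell in APOEhi and rose in APOElo were IGFBP3 (-5.66, SE 0.13), RGS4 (-5.22, SE 0.32) and the interleukin 1 receptor antagonist IL1RN (-1.10, SE 0.12). Values per library were not used here, so it was not checked whether a single library carries any of these differences. No explanation of them was tested.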

How the results depend on the processing

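Alternatives chosen only after the data were seen were median-centred fold changes, protein-coding genes only, entries set aside put back as deposited or with statistic times SE, shared control error removed, other list statistics, and APOE levels taken across the tables. Counts of called genes stayed within 1.5 times of the reported ones under every other filter, scaling or treatment of entries run, from 6948 to 8312 in APOEhi, 7252 to 8042 in APOElo and 3500 to 3994 between APOEhi and APOElo. A minimum log2 fold change of 1 left 2420, 2108 and 823 genes, and 997 called in the same direction in both, fewer by its construction. Removing the shared control error gave 6010 genes between APOEhi and APOElo, since its standard error is smaller. With fold changes in place of the statistic, 9, 9 and 12 lists passed instead of 19, 21 and 24, and the cause was not tested. The log2 fold change of APOE was 1.51 in APOEhi and 6.60 in APOElo with the control level of the other table, and 0.70 between APOEhi and APOElo with their levels, from tables normalized separately, set side by side; the cause was not tested. The balance of higher and lower genes turned from 52.5% to 34.6% higher in APOEhi, and from 56.6% to 28.7% between APOEhi and APOElo, with library totals. No named gene past the threshold changed sign. No list called under both settings changed direction, but those that lost the call and turned were lipid-associated macrophages in APOElo (ranks, adjusted p = 0.689), fatty acid synthesis in APOElo (adjusted p = 0.932) and matrix genes between APOEhi and APOElo (adjusted p = 0.917), both with fold changes. Of 1654 pairs of a named gene and an alternative, 1619 kept their direction and side of the threshold, 19 lost the call and 16 gained one. No paired analysis was possible because the tables hold no values per library, although the labels number the replicates alike. For that reason other normalizations (RLE, upper quartile), other tests, another pseudocount, fits of all 9 or only the 6 libraries compared, leaving out each replicate, an estimated correlation, fry and other splits of the samples were not run. Depth limits genes with few control reads, such as SERPINB4. In simulated data the difference test called 22 of 50 genes that differed by 0.5. Those genes were not drawn from the lowest counts, so the rate does not cover genes with few reads.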

Other observations

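Chosen only after the results were seen were the pathway tests of this part, the tests of renal RNA in APOElo alone and of an interleukin response in APOEhi alone, the interleukin test with the left-out genes and its margin of 1 standard deviation, both tests of the table entries and both tests with the cell cycle list. Among KEGG pathways of protein-coding genes with 15 to 300 tested members, cameraPR called 4 in APOEhi, 5 in APOElo and 43 between them. In APOEhi, circadian rhythm genes rose (15 of 29, with 4 falls, median 0.35, adjusted p = 0.0214). In the authors' deposited table, the clock repressors NR1D1 and PER1 stood at 2.60 and 2.27. The pathway of protein processing in the endoplasmic reticulum also rose (89 of 202, with 34 falls, adjusted p = 8.3e-04), as did PPAR signalling (22 of 54, with 11 falls, adjusted p = 0.0329).

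In APOElo, the pathway of matrix and receptor interaction rose (32 of 88, with 17 falls, median 0.25, adjusted p = 0.0360). In the authors' deposited table, the integrin subunit ITGB3 stood at 4.31 and the collagen chain COL6A3 at 3.93. Glycan degradation fell (13 of 19, with 0 rises, median -0.32, adjusted p = 0.0269), with the fucosidase FUCA1 at -1.12 in the authors' deposited table. TGF-beta signalling, with TGFB1, TGFBR1 and TGFBR2 set aside, was lower in APOEhi than in APOElo (18 of 76 lower and 8 higher, median -0.20, adjusted p = 0.00658), and glyoxylate and dicarboxylate metabolism was higher (16 of 30, with 0 lower, median 0.55, adjusted p = 2.9e-04). These genes and pathways were chosen after their values were seen.

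The rises of SERPINB4 and CCL26 were shared by both comparisons. More RNA from the HK-2 cells than in control would raise renal epithelial genes by a median of at least 0.5. In APOEhi their median was -0.57 with the list not called (cameraPR, adjusted p = 0.334), which argues against more such RNA there. Control macrophages also shared medium with HK-2 cells. An equal amount of such RNA in all groups would leave the list flat, so this test cannot exclude it. In APOElo the median was 0.59 with the list not called, and the abundant keratins KRT8 and KRT18 stood at -0.69 and -1.48 without a call in the authors' deposited table, so such RNA stays open for APOElo. Both genes respond to interleukin 4 and interleukin 13, and such a response in both comparisons needed, as set beforehand, a median of at least 0.5 over 18 further target genes in each. That bound was missed in APOElo by more than the bootstrap standard deviation (median of the 17 tested 0.092, standard deviation 0.34, 2364 of 10000 random lists as high). With the alternative activation genes the 18 had left out, the median was 0.09 (34 tested, 13 up and 8 down, standard deviation 0.26). This adds no separate test, since the 17 are among the 34 and the added genes alone had a median of 0.09. CameraPR gave those added genes a rise in APOElo (adjusted p = 1.2e-08). That call ended with ranks of the statistic (adjusted p = 0.372). Of the 17 in APOElo, 5 rose and 3 fell, from HOMER2 at 2.06 to CISH at -1.53 in the authors' deposited table. ALOX15 and TGM2 stood at 3.82 and 4.05 in APOElo in the authors' deposited table. Members went in both directions and the margin of 1 standard deviation was set afterwards, so the median does not decide on a response shared by both. In APOEhi the median was 0.499, under the bound but within its bootstrap standard deviation of 0.37 (13 of 10000 random lists as high), so a response in APOEhi alone stays open.

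In 70 entries the listed fold change was not the statistic times SE. A second fit or shrinkage would give gaps without a pattern, but 54 of the 70 were multiples of 0.1, which argues against it. With statistic times SE the control levels of 44 of the 48 such genes that could be compared matched between the tables, against 5 with the listed values. This is consistent with values in the fold change column having changed after the statistics were computed, by a step the tables do not record. Other columns held faults as well. The deposited p-value did not follow from the statistic in 1 entry of each table, and the adjusted p-value did not follow in 2 entries for APOEhi and 1 for APOElo. In APOEhi, TGFBR1 had a deposited p-value of 8.4e-04 where its statistic gives 0.118. CD163 there had a deposited adjusted p-value of 0.171, below its p-value of 0.215. How these faults came about was not tested, and no biological explanation applies.

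Progenitor-type genes fell in both comparisons, with medians of -2.15 and -2.14. Fewer cells left undifferentiated in the VHL-knockdown arm would lower cell cycle genes as well. In APOElo these rose instead, with a median of 0.22 (cameraPR, adjusted p = 6.6e-04, or 0.499 with fold changes in place of the statistic). Each library pools the RNA of many cells, so a rise in the other cells could hide a loss of undifferentiated ones. The test therefore cannot decide for APOElo. In APOEhi the cell cycle median was -0.017 with members in both directions (adjusted p = 0.999), which decides nothing. Fewer undifferentiated cells stay open for both groups. No other explanation of the fall was tested.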
